A study of Mus musculus with 6 samples.

How the data were processed

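RNA was measured on 6 Affymetrix whole-transcript arrays hybridised with RNA of C2C12 cells, an established mouse myoblast line that forms myotubes when serum is lowered. The labels give 2 groups of 3 arrays, one transfected with a control siRNA and one with an siRNA against the mouse H19 transcript. Per the labels, cells grew in medium with 10% fetal bovine serum and were moved at about 90% density to medium with 2% horse serum. Transfection was at day 1 of differentiation and RNA was taken 40 h later. The transfections were made in triplicate, and nothing states that the triplicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

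The deposited values are log2 expression values per probe set, made by the authors with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA corrects background, normalises between arrays by quantiles and summarises the probes of a probe set on the log2 scale, so small fold changes are compressed towards 0 near background. The software version and the probe set annotation the authors used are not given in the sources used here. The table held 35556 rows and 6 sample columns, with medians between 6.73 and 6.78 on the 6 arrays, and the scale fits log2 because every value lay between 2.97 and 14.6. The values were neither centred per gene nor expressed as ratios. Scanner intensities and detection calls were not used here, so probe sets near background could not be marked as such, and precision is limited by the number of arrays.

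Probe sets were named from GEO's platform annotation. Of the 35556 rows, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Gene identifiers of 21698 single-symbol probe sets matched the RefSeq gene table for GRCm38.p6, and 0 symbols needed an update. Where a gene had several probe sets (999 genes), the one with the highest mean over all 6 arrays stood for it. Probe sets with several symbols stayed in as unnamed units. This left 21559 units, of which 19938 were genes with 1 symbol. No probe set was listed under the symbol H19, so the targeted transcript was followed through a probe set listed under both Mir675 and Supt6. Mir675 lies inside the H19 gene in the RefSeq table.

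H19 siRNA was compared with control siRNA by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, over all 6 arrays, with no covariate, no filter on dim probe sets and a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values below come from this fit unless another test is named. Fold changes are differences of mean log2 values, H19 siRNA minus control siRNA, with the moderated standard error, and group values are mean ± SD with n = 3. The test, the 30 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Of the 764 list entries 682 had a measured gene, and the others were not analysed here. Older symbols were followed only where the written symbol is not itself the current symbol of a gene, a matching step corrected after the values were seen, which took 1 wrongly matched gene each from the matrix and the glycolysis lists. Lists were tested with camera (preset inter-gene correlation of 0.01, two-sided, Benjamini-Hochberg over the 30 lists), which compares a list's genes with all other genes. They were tested again with a correlation estimated per list and with fry, which tests whether the genes of a list move one way. With an estimated correlation camera also refers its statistic to the 4 residual degrees of freedom of a gene. With the preset it uses degrees of freedom close to the number of units. A call lost with an estimate therefore does not by itself point to correlation among genes. Counts "adjusted over the list alone" correct the limma p-values over the members of a list.

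The rule for named genes took the targeted transcript, the 8 largest increases and the 8 largest decreases among called single-symbol genes whose 3 arrays of one group all lay beyond all 3 of the other, 11 genes chosen in advance (Hmga2, Dicer1, Igf2bp2, Smad1, Smad5, Cdc6, Igf2, Myod1, Myog, Myh3 and Ckm) and up to 4 members with the smallest p of each list described. Predicted genes, clone names, receptors of the olfactory and vomeronasal families and small RNAs were passed over in the lists of 8. Igf2bp2 was not analysed here. Other genes are named only as chosen after their values were seen.

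The 6 arrays were compared before averaging. Pearson's r across all rows lay between 0.9958 and 0.9975 for the 15 pairs, and no pair was identical. The second H19 siRNA array stood slightly apart, with a mean r of 0.9962 to the others. The labels give no scan date or batch.

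The fit was tested on 10 simulated sets with the real means of the 21559 units, 3 against 3 arrays and 200 changed genes. Noise was drawn independently for each unit from its moderated variance, which limma pulls towards a common value. The fit called 43.6% of genes changed by 0.25 on the log2 scale, 96.4% of those changed by 0.5, 99.8% of those changed by 1 and 100% of those changed by 2, and 4.92% of its calls were unchanged genes. These shares hold for the simulated settings only. In the real comparison no called unit changed by less than 0.26. With nothing changed the fit called 0 genes and camera 0 lists, and a list raised by 0.25 was called in 10 of 10 sets. Because the simulated genes were independent, the list results do not show how camera behaves with correlated genes. Estimated correlations of the real lists reached 0.40. Alternatives were a second quantile normalisation, median centring, an intensity trend with robust variance, array weights, filters at the 30th percentile and at the median of all rows, the mean of a gene's probe sets, all rows without collapsing, a minimum fold of 1.5, a test against a fold of 1.2 (treat), the replicate number as a block, and leaving out each array in turn. Tables were handled and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.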

Results

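Expression was profiled in differentiating C2C12 myoblasts that were transfected on day 1 of differentiation with a control siRNA or with an siRNA against H19 and collected 40 h later, with 3 arrays per group. H19 is an imprinted long noncoding RNA that hosts the microRNA miR-675 and carries binding sites for let-7 microRNAs. The single comparison of the design asks which transcripts differ when H19 is depleted in differentiating muscle cells.

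The signal closest to H19 was lower in every H19 siRNA array. No probe set was listed under H19 itself, and Mir675 is hosted by H19. The probe set listed under Mir675 and Supt6 (10569341) read 12.21, 12.22 and 12.27 on the 3 control arrays and 10.38, 10.28 and 10.37 on the 3 H19 siRNA arrays. It fell by 1.89 on the log2 scale (SE 0.04), or 3.71-fold, to 26.9% of the control level, with an adjusted p of 1.80e-05 in limma, the smallest of all units. Supt6, a transcription elongation factor gene on another chromosome, has a probe set of its own that read 10.41 ± 0.02 and 10.35 ± 0.04 (SD, n = 3 each), with a limma adjusted p of 0.594. Igf2, the imprinted growth factor gene neighbouring H19, read 8.64 ± 0.04 with control siRNA and 8.66 ± 0.03 with H19 siRNA (SD, n = 3 each), a difference of 0.02 on the log2 scale with a 95% interval from -0.07 to 0.11. An exact permutation test of 3 against 3 arrays cannot go below 0.1, the value that the Mir675 and Supt6 probe set reached (two-sided).

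Among genes with 1 symbol, the called changes were small in size. Of 21559 units, 43 passed an adjusted p of 0.05 in limma, 27 higher and 16 lower with H19 siRNA. They included 41 genes with 1 symbol, 26 higher and 15 lower, and none of these 41 changed by more than 1.96-fold upward or 1.93-fold downward. Of the 43 units 9 changed by 1.5-fold or more. Probe sets that the annotation does not list were outside this comparison, and over all rows 4 of them passed. They differed by up to 2.42 on the log2 scale, the widest from a control level of 4.33, below the 30th percentile of all rows. Groups did not overlap for 17.6% of all units, against 10% expected by chance for 3 against 3. The count depended on the variance model, on the filter for dim probe sets and on all 6 arrays. It was 435 with an intensity trend and robust variance (55.6% higher), and 214 and 75 with filters at the median and at the 30th percentile. It was 1, 3 and 4 without control siRNA replicates 1, 2 and 3, and 2, 21 and 1 without H19 siRNA replicates 1, 2 and 3. Leaving out an array also left fewer degrees of freedom. Units with an unadjusted limma p under 0.05 then ran from 1665 to 2612, against 2340 with all 6 arrays. After centring each array on its median, 36 units passed, 19 higher and 17 lower.

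The largest increases were in Heyl, a Notch-induced transcriptional repressor, and in interferon-inducible genes. Heyl rose from 8.54 ± 0.07 to 9.51 ± 0.14 (SD, n = 3 each), a 1.96-fold increase. Usp18, a protease that removes ISG15 from proteins, rose 1.81-fold from 8.52 ± 0.10 to 9.38 ± 0.05. Ifit3 and Ifit1, related antiviral proteins, rose 1.76-fold and 1.60-fold, and Oasl2, of the oligoadenylate synthetase family, rose by 0.59 on the log2 scale. Ifi27l2a, also interferon-inducible, rose 1.48-fold. Rdh5, a retinol dehydrogenase, rose 1.43-fold, and Lgals3bp, a secreted glycoprotein, rose 1.42-fold. Limma adjusted p-values of these 8 genes ran from 0.00404 for Ifit1 to 0.0425 for Lgals3bp.

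The largest decreases included lumican and decorin, small proteoglycans of the collagen matrix. Lum fell by 0.95 on the log2 scale (SE 0.09), from 7.40 ± 0.02 to 6.45 ± 0.19 (SD, n = 3 each). Dcn fell by 0.50 (SE 0.03), from 12.71 ± 0.02 to 12.21 ± 0.02. Tslp, a cytokine, fell by 0.69, and Saa3, an acute-phase protein, fell by 0.61. Wfdc17, a small secreted protein, fell by 0.56. Hsd11b1, which activates glucocorticoids, fell by 0.50, Thbd, the thrombin receptor thrombomodulin, fell by 0.49, and Stx12, an endosomal syntaxin, fell by 0.44. Limma adjusted p-values of these 8 genes ran from 0.00648 for Saa3 to 0.0425 for Thbd.

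**Figure D1:**
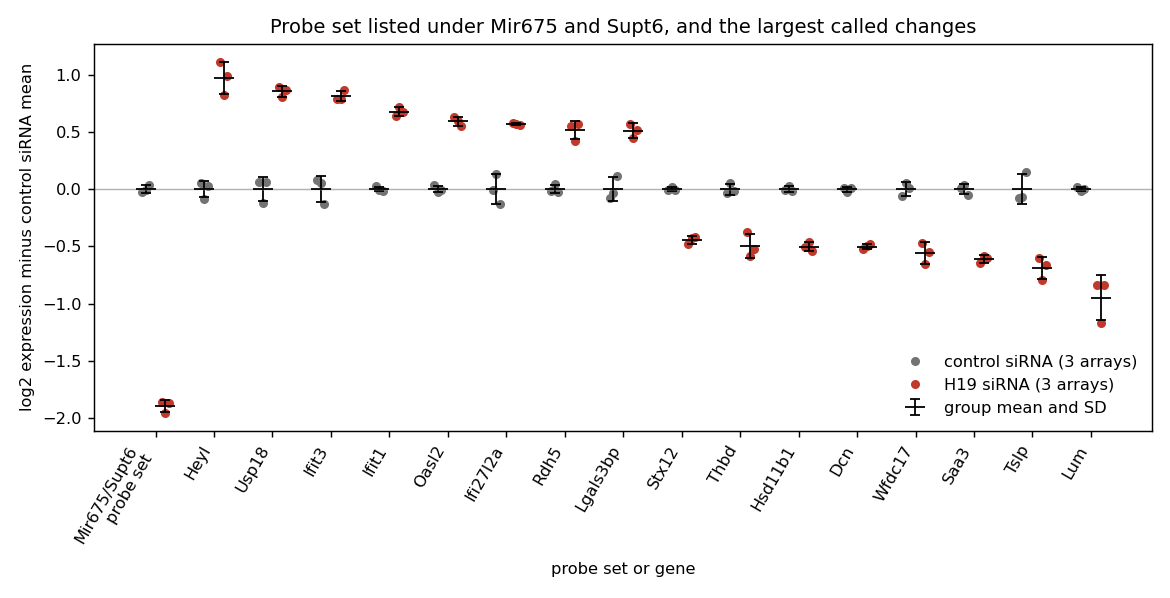
Log2 expression minus the control siRNA mean (y axis) for the probe set listed under Mir675 and Supt6 and for the 8 largest called increases and 8 largest called decreases (x axis). Points are single arrays (3 per group), and bars are the group mean and SD; the Mir675 and Supt6 probe set lies at -1.89, further from control than any named gene, the nearest being Heyl at 0.97 and Lum at -0.95.

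The interferon response list was higher as a group. All 26 measured members had a positive fold change, with a median of 0.27 on the log2 scale. Over all genes 7 members rose (Usp18, Ifit3, Ifit1, Oasl2, Xaf1, Bst2 and Cxcl10) and 0 fell, and adjusted over the list alone 21 rose and 0 fell. Camera gave the list an adjusted p of 6.95e-29 with the preset correlation. With an estimated correlation of 0.10 the adjusted p was 0.0708, and fry gave an adjusted p of 0.00155. The NF-kB and cytokine list had a median of 0.01 and a camera adjusted p of 0.491, with 0 members passing over all genes. Its members with the smallest p went both ways, Cxcl1 at -0.18 and Cxcl5 at -0.19 against Lif at 0.22, and 3 members passed adjusted over the list alone (1 higher, 2 lower). Macrophage and leukocyte markers had a median of 0.04 and a camera adjusted p of 0.918. Ifit3 has a close copy, Ifit3b, whose separate probe set differed by 0.48 (limma adjusted p = 0.295), and hybridisation between the copies cannot be excluded.

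Muscle genes were slightly higher as groups, mostly below the threshold for single genes. Of 47 sarcomere and contractile genes 1 rose over all genes, Tnnt2 (the troponin T form of developing muscle), from 12.45 ± 0.02 to 12.71 ± 0.01, an increase of 0.26 on the log2 scale with a limma adjusted p of 0.0425 that became 0.0976 after median centring. Adjusted over the list alone 8 rose and 0 fell, among them Mybph (0.16), Actn3 (0.15) and Mylpf (0.13). The list's median was 0.05, with a camera adjusted p of 0.0279 and a fry adjusted p of 0.00772. The camera adjusted p was 0.248 with an estimated correlation, although that estimate was 0.0032, below the preset 0.01. Of 41 genes for calcium handling, the neuromuscular synapse and energy supply 0 passed over all genes and 11 rose adjusted over the list alone, led by Sgca (0.27), Jph2 (0.25), Rapsn (0.32) and Mb (0.20). That list had 33 members with a positive fold change, a median of 0.10 and a camera adjusted p of 2.73e-07, which was 0.248 with an estimated correlation of 0.11, and a fry adjusted p of 0.0153. Sgca, Jph2 and Rapsn passed over all genes with an intensity trend, with array weights and with both filters on dim probe sets. Myh3, embryonic myosin, differed by -0.03 with a 95% interval from -0.12 to 0.07, and Ckm, muscle creatine kinase, by 0.10 with an interval from -0.01 to 0.21. The sarcomere list also missed the threshold with the replicate number as a block (adjusted p = 0.0970) and without control siRNA replicate 3 (0.111), H19 siRNA replicate 1 (0.0801) or H19 siRNA replicate 2 (0.0576). Its median was 0.03 after median centring, after a second quantile normalisation and without control siRNA replicate 2.

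Lists of regulators on both sides of muscle differentiation were higher. Among 18 promyogenic regulators 0 passed over all genes and 6 rose adjusted over the list alone. The 2 master regulators Myog and Myod1 differed by 0.22 (SE 0.03) and 0.23 (SE 0.04), with limma adjusted p-values of 0.0779 and 0.0965 over all genes, and every H19 siRNA array lay above every control array for both. Both passed with an intensity trend and with the filter at the median. Rbm24, an RNA-binding splicing regulator of muscle, differed by 0.29 and Mef2d by 0.23. The list had a median of 0.10 and a camera adjusted p of 8.19e-05, which was 0.274 with an estimated correlation of 0.16, and a fry adjusted p of 0.0153. The 21 progenitor and antimyogenic regulators had a median of 0.10 too, with a camera adjusted p of 0.000262 that was 0.248 with an estimated correlation, and a fry adjusted p of 0.00772. Without H19 siRNA replicate 3 the median was 0.0605. Of these Heyl and Sox8 rose over all genes, Sox8 1.32-fold (limma adjusted p = 0.0227), and 5 rose adjusted over the list alone, Pax7 (0.24) and Hes1 (0.22) among them. The fusion and adhesion list (27 genes) had a median of 0.02 and a camera adjusted p of 0.674. Its member with the smallest p was Cdh15, M-cadherin, at 0.28 with a limma adjusted p of 0.0519, followed by Mymk, the membrane activator of myoblast fusion, at 0.19. Adjusted over the list alone 3 members rose and 1 fell.

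The Notch and Wnt list and the matrix list passed camera with the preset correlation but not with an estimated one. Among 27 Notch and Wnt genes, which share Hes1, Hey1 and Heyl with the antimyogenic list, 22 had a positive fold change, Heyl alone passed over all genes, and adjusted over the list alone 7 rose and 3 fell, with the Notch ligand Dll1 at 0.32, Ccn4 at 0.17 and the Wnt antagonist Sfrp1 at -0.35. The camera adjusted p was 0.0113 with the preset correlation and 0.248 with an estimated one, and fry gave 0.00687. The estimate was 0.0086, below the preset 0.01, so a higher correlation among its genes is not why that call was lost. The run with an estimate used only 4 residual degrees of freedom, which raised the p. The list's median of 0.07 was 0.0456 without H19 siRNA replicate 2. Of 39 extracellular matrix genes 19 had a positive and 20 a negative fold change. Lum and Dcn fell over all genes and 0 rose, and adjusted over the list alone 6 fell, Tgfbi (-0.21) and Col12a1 (-0.17) among them, and 1 rose. The matrix list's median was close to 0 at -0.0044 and its mean was -0.05. Its camera adjusted p was 0.0259, or 0.796 with an estimated correlation of 0.18, and its fry adjusted p was 0.0869. The camera call was lost with array weights (adjusted p = 0.0677), with filters at the 30th percentile (0.0517) and at the median (0.165), and without H19 siRNA replicate 2 (0.0948) or replicate 3 (0.0602), and the median was 0.0020 without control siRNA replicate 3. Smooth muscle and myofibroblast markers had a median of 0.05 (camera adjusted p = 0.0594, or 0.274 with an estimated correlation), and passed in fry (0.0233) and in 4 of the alternatives for camera.

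Cholesterol synthesis and replication-dependent histone genes passed camera as lists with the preset but not with an estimated correlation, with no single member past the threshold. All 18 measured cholesterol genes had a positive fold change, none beyond 0.11, with a median of 0.06 and a camera adjusted p of 0.000905 that was 0.248 with an estimated correlation, and a fry adjusted p of 0.0233. The members with the smallest p were Fdps (0.09), Srebf2 (0.10) and Fdft1 (0.08), for which a second probe set gave 0.006. Of 22 histone genes 19 had a positive fold change, with a median of 0.05 and a camera adjusted p of 0.00395 that was 0.276 with an estimated correlation, and the list missed the threshold in fry (adjusted p = 0.0581). H1f1 differed by 0.15 and H2ac4 by 0.20. In both lists 0 members passed over all genes, and 0 adjusted over the list alone. After median centring the medians were 0.0344 for cholesterol and 0.0299 for histone genes, with both lists still past at the preset correlation. Histone genes are near-identical copies, so probe sets may not tell them apart.

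Targets of microRNAs tied to H19 did not pass the list test. Of 36 let-7 targets 0 passed over all genes and 0 adjusted over the list alone, 17 had a positive fold change, and the median was -0.0039 (95% bootstrap interval over genes, which are not independent, -0.03 to 0.03) with a camera adjusted p of 0.613. Hmga2, a chromatin protein and let-7 target, differed by -0.05 with a 95% interval from -0.13 to 0.04. Dicer1, the microRNA-processing nuclease, differed by -0.11 with an interval from -0.21 to -0.01 and lay lower on every H19 siRNA array, with a limma adjusted p of 0.408. Myc (0.13), Cdk6 (-0.14) and Ccnd2 (0.14) had the smallest p of the list and went both ways. The 4 miR-675 targets had a camera adjusted p of 0.798. Smad1 differed by 0.04 (95% interval -0.06 to 0.15), Smad5 by -0.02 (-0.10 to 0.07) and Cdc6, a replication licensing factor, by 0.25 (0.03 to 0.47, limma adjusted p = 0.402). Of 13 microRNA pathway genes 0 passed, with a camera adjusted p of 0.202.

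Among 23 imprinted genes Dcn, which is also in the matrix list, fell over all genes, and adjusted over the list alone Mest rose (0.19) as well. The list had a camera adjusted p of 0.658. Proliferation genes did not pass: the mitosis list (42 genes) had a median of -0.01 and a camera adjusted p of 0.102. That adjusted p went both ways, to 0.0141 without H19 siRNA replicate 3 and to 0.488 with array weights. The DNA replication list (36 genes) had a median of 0.02 with a camera adjusted p of 0.674. The unfolded protein and amino acid stress list was at a camera adjusted p of 0.0542. It passed in fry (0.0206) and in 6 of the alternatives for camera, from 0.00176 with an intensity trend to 0.0472 with array weights. In camera it was at 0.148 after median centring and at 0.350 with an estimated correlation. Ddit3 differed by 0.15 and Trib3 by 0.19, and 4 members rose and 1 fell adjusted over the list alone. Camera adjusted p-values were 0.613 for oxidative phosphorylation genes, 0.658 for glycolysis and hypoxia genes, 0.798 for ribosomal protein genes, 0.798 for p53 response genes, 0.978 for immediate early genes and 0.731 for BMP and TGF-beta response genes, with 0 members of these 6 lists passing over all genes. Markers of other cell types gave 0.613 for adipocytes, 0.674 for bone and cartilage, 0.697 for endothelium and 0.798 for neurons and glia, also with 0 members passing. In the DNA replication, BMP and TGF-beta, p53, NF-kB and cytokine, bone and cartilage and imprinted lists the median was above 0 while camera, which compares with all other genes, pointed downward, and the mean was below 0 in the NF-kB and cytokine, bone and cartilage and imprinted lists. In the let-7, immediate early, endothelial and neuron and glia lists the median was below 0 and the mean above 0.

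In all, 9 of 30 lists passed camera with the preset correlation, 8 higher and 1 lower. With an estimated correlation and the 4 residual degrees of freedom of that run, 0 lists passed and 6 had an unadjusted p under 0.05. Fry called 9 lists, all higher, of which 7 were among those that camera called. Unlike camera, fry does not compare a list with other genes, and it was run on the deposited values only. The median log2 fold change of all units was 0.0137, and such a general shift counts towards the calls of fry.

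**Figure D2:**
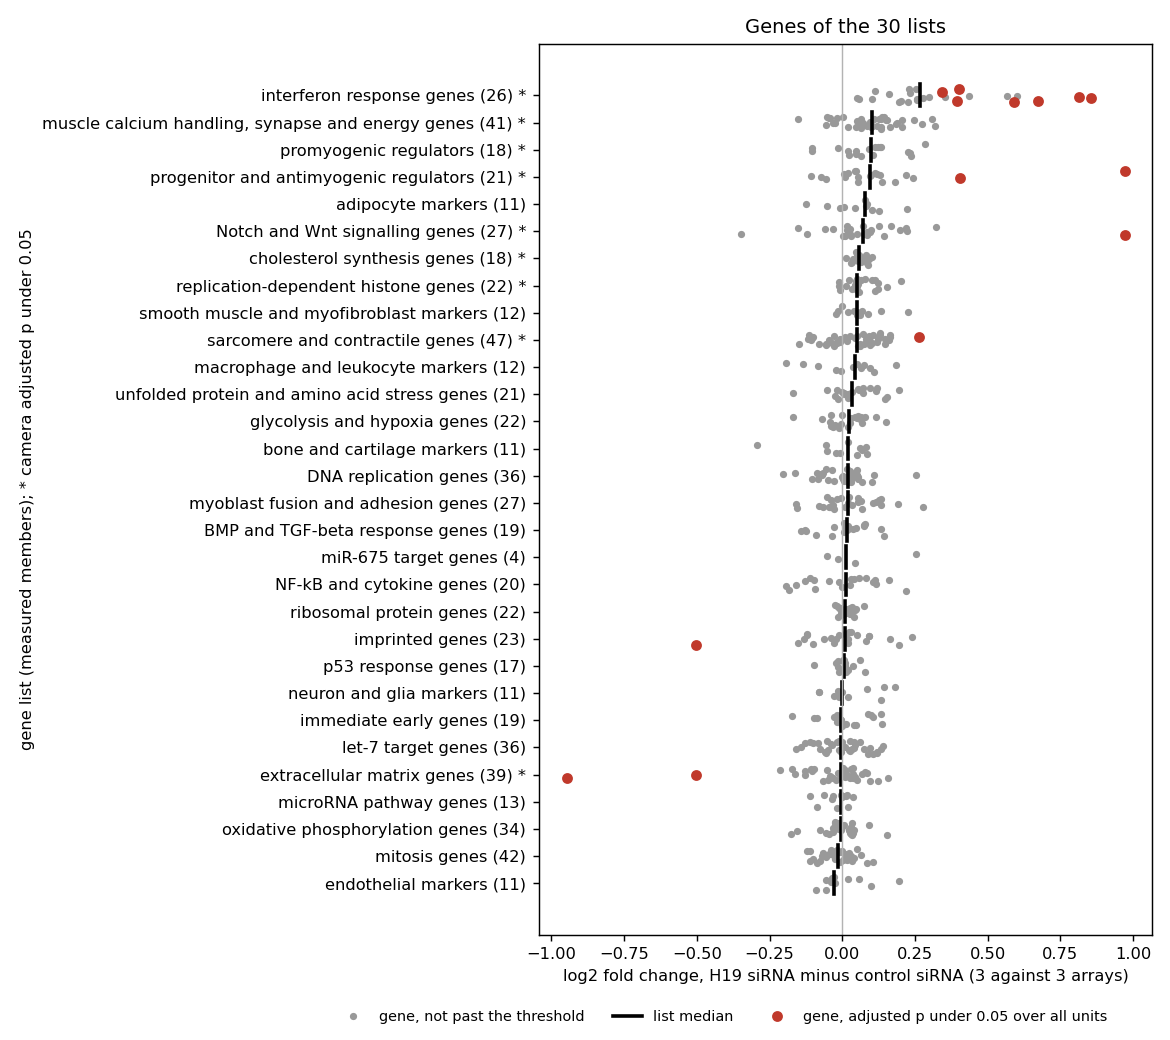
Log2 fold change, H19 siRNA minus control siRNA (x axis), of each measured gene of the 30 lists (y axis, number of members in brackets), 3 against 3 arrays. Grey points did not pass the threshold over all units, red points did, black bars are list medians, and asterisks mark camera adjusted p under 0.05; the interferon list has the highest median (0.27) and lies wholly above 0.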

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

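The tests of a single array and of scaling for the interferon list were set before their results were seen, and the tests of the muscle lists, of a response to the siRNA duplex and of other splits were written down after. The signals below come from probe sets that the platform annotation does not list, which were left out of the main fit and entered only the fit over all rows. Of 12146 such probe sets, 4 passed an adjusted p of 0.05 in limma over all 35556 rows, 3 higher and 1 lower with H19 siRNA. Probe set 10582916 was higher by 2.42 on the log2 scale, from 4.33 ± 0.07 to 6.76 ± 0.22 (SD, n = 3 each), a wider difference than any named gene showed. Probe set 10485357 was higher by 1.81, from 10.40 ± 0.05 to 12.21 ± 0.08. Probe set 10502791 was higher by 0.64, from 9.42 ± 0.03 to 10.06 ± 0.02. Probe set 10569335 was lower by a log2 fold change of -1.57, from 12.96 ± 0.01 to 11.39 ± 0.07, or 33.6% of the control level, against 26.9% for the probe set listed under Mir675 and Supt6, and it may measure the targeted transcript itself. The genes behind these 4 probe sets were not identified here.

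The interferon response genes were higher with H19 siRNA. The list's camera call was lost with an estimated correlation (adjusted p = 0.0708), a run that also used only 4 residual degrees of freedom. A single array as the source is argued against, since the list's median stayed at 0.25 or more on the log2 scale with each array left out, against 0.27 with all 6. Scaling between arrays is argued against too, since the smaller median after quantile normalisation or median centring was 0.246. A response to the siRNA duplex itself, rather than to the loss of H19, stays open and cannot be told apart from it. The labels give 1 name for the siRNA against H19, and 2 or more separately labelled siRNAs would be needed. A biological effect of H19 on interferon genes stays open on the same ground.

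The muscle gene lists were slightly higher with H19 siRNA, though the camera calls of both were lost with an estimated correlation (adjusted p = 0.248 for each). That estimate was 0.11 for the calcium handling, synapse and energy list but 0.0032 for the sarcomere list. The latter is below the preset 0.01, so a higher correlation among its genes is not why its call was lost. What raised its p was the lower degrees of freedom of that run, 4 in place of close to the number of units. For the list of calcium handling, synapse and energy genes a single array is argued against by a smallest median of 0.0814 with 1 array left out, against 0.102 with all 6, and scaling by a median of 0.0799, the smaller of those after median centring and quantile normalisation. The sarcomere list was less steady. Its median of 0.0492 was 0.0268 after median centring, 0.0321 after quantile normalisation and 0.0299 without control siRNA replicate 2. Its call was lost without control siRNA replicate 3, H19 siRNA replicate 1 or H19 siRNA replicate 2, so neither source is set aside for it. That more cells had left the cell cycle may be a biological account of the shift, and it stays open, because the mitosis list had a camera adjusted p of 0.102, the DNA replication list one of 0.674 with 23 of 36 members positive, and the share of differentiated cells, which sets how far cycle genes would fall, is not known. The replication-dependent histone list, whose genes are expressed mainly in S phase, was higher in camera (adjusted p = 0.00395), though not with an estimated correlation (0.276). An effect of H19 depletion on differentiation was not tested apart from an effect of the duplex.

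Other splits of the 6 arrays were set against the real one. The real split gave 43 units past the threshold and the highest of the other splits gave 0, and 1 of the 10 splits, the real one, gave as many. Each other split put arrays of both siRNAs in each group, so any difference between siRNAs added to the spread within groups there. The 0 units therefore do not measure what chance alone would give. For gene lists in camera the real split gave 9 and the others gave from 0 to 6, again with 1 of 10 as large. Those splits mixed both siRNAs in the same way, so their list counts do not measure what chance alone would give either. With 10 splits a share under 0.05 cannot be reached.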

How the results depend on the processing

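All alternatives were set before the data were examined. The signal of the probe set listed under Mir675 and Supt6 kept its direction and stayed past the threshold in all alternatives run. The count of 43 units past the threshold was 60 after a second quantile normalisation, 36 after median centring and 43 with the mean of a gene's probe sets, and moved further elsewhere. It was 435 with an intensity trend and robust variance, 214 and 75 with filters at the median and at the 30th percentile, 70 with array weights, 11 over all rows, 9 with a minimum fold of 1.5 and 1 in the treat test against a fold of 1.2. All 43 units remained among the 435, the 75 and the 70, and 39 among the 214. Leaving out 1 array gave from 1 to 21 units, with 20 of the 21 shared, where fewer samples left fewer degrees of freedom. With the replicate number as a block 3 units and 8 lists passed, the sarcomere list being the one lost. The numbers were not taken to pair the samples, since deviations of same-numbered arrays from their group means correlated at 0.00, -0.07 and -0.11 and not every array correlated best with its own number. Of 18 named calls, 18 held after quantile normalisation and with the trend, the weights, both filters and the probe set mean, and 17 after median centring, where Tnnt2 was lost. Only 8 held with the minimum fold of 1.5, 2 with the block and 0 in treat, and 0, 2 and 3 without control siRNA replicates 1, 2 and 3 and 1, 12 and 0 without H19 siRNA replicates 1, 2 and 3. Of the named genes not called, 32 of 111 passed with the trend, 17 of 93 with the median filter, 5 of 106 with the 30th percentile filter, 5 of 111 with the weights and 2 after quantile normalisation. The 9 lists past camera became 0 with an estimated correlation, and 7 to 11 lists passed in the other alternatives, leave-one-out included. For the sarcomere (0.0032) and the Notch and Wnt (0.0086) lists the estimate was below the preset 0.01, so higher correlation is not why they were lost. Using an estimate also cut the degrees of freedom of camera to the 4 of a gene's residual, for all lists. Medians of 18 of the 30 lists changed sign in 1 or more alternatives, 10 of them after median centring, and of these 18 only the matrix list had passed. Uncalled gene differences that changed sign were Igf2 after median centring (-0.0014) and Smad5, which ranged from -0.0291 to 0.0102 with 1 array left out. Apart from the fewer samples, rows or degrees of freedom named, the cause was not tested. Depth does not apply to arrays, and without detection calls the dim probe sets could not be set apart.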

Other observations

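Several called genes outside the fixed lists, named here after their values were seen, are known to respond to interferon. Oas2, of the oligoadenylate synthetase family, rose 1.34-fold and Iigp1, an immunity-related GTPase, rose 1.36-fold, with limma adjusted p-values of 0.0402 and 0.0490. A unit listed under both Irgm2 and Igtp, 2 further GTPases of that family, rose 1.46-fold (limma adjusted p = 0.0239).

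Other called genes, a part of those outside the rule and likewise named after their values were seen, had varied functions, and no shared theme was tested. Mylk2, the skeletal muscle myosin light chain kinase, rose 1.31-fold and Dio2, which activates thyroid hormone, rose 1.35-fold. Chchd10, a mitochondrial protein, rose 1.24-fold, and the secreted proteins C1qtnf3 and Fbln7 rose 1.23-fold each. Ptn, the growth factor pleiotrophin, fell by 0.39 on the log2 scale, Slpi, a secreted protease inhibitor, fell by 0.32, and Srp19, a subunit of the signal recognition particle, fell by 0.44. Limma adjusted p-values of these 8 genes ran from 0.0151 for Ptn to 0.0425 for C1qtnf3 and Fbln7.

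Mir483, hosted by Igf2, read between 7.32 and 7.46 on 5 arrays and 8.01 on H19 siRNA replicate 2, and its group difference of 0.26 did not pass (limma 95% interval -0.09 to 0.61).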
